A study of Candida albicans with 7 samples.

How the data were processed

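The data were 7 Agilent tiling arrays of 2 colours, each with ORC ChIP DNA and whole-cell-extract genomic DNA of 1 log-phase culture. The labels describe the 7 as different unsynchronised cultures, so each array was 1 replicate of 1 group. The direction of every ratio was taken from the dyes in the labels, with ChIP in Cy3 on 4 arrays and in Cy5 on 3. The file headers place arrays 1 to 4 on slide 1 and arrays 5 to 7 on slide 2, with both orientations on each slide.

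The deposited scanner files hold spot intensity for both channels. Per the file headers, the authors used Agilent Feature Extraction 10.5.1.1 with its CGH protocol, and the processed intensity is background-subtracted, spatially detrended and dye-normalised by the linear method. The same files give raw median spot intensity and local background, per the file headers, without correction. The authors' deposited value table is a score per probe with no stated scale. Set against the scanner ratio of the same array, the authors' score rose with ChIP over whole-cell extract on all 7 arrays (r = 0.79 to 0.89 across probes), so its direction was settled. Its column medians were −0.053, −0.011, −0.043, −0.0075, −0.013, −0.0092 and −0.0026 on arrays 1 to 7, so it was centred near 0, and its log base and scaling stay unknown. It was used only as an alternative. The genome build of the probe names is not given in the sources used here.

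The 176771 genomic probes included 152 on 4 sequences outside the 8 chromosomes, which were kept out of the tests. The probe names number the chromosomes 1 to 8, and they were named R and 1 to 7 here by the order of their probed spans, set against the spans of the gene table of RefSeq assembly ASM18296v3. That table was used for nothing else, because the build of the array is not named. So sites were not set against genes, tRNA genes, centromeres, intergenic regions, base composition or motifs, and the tests planned for these, with the gene lists, were not run.

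Log2 ratios of the processed intensities were turned to ChIP over whole-cell extract. Spots flagged as outliers (49 to 899 per array) were left out, and each array was centred on its median over chromosome probes, with no loess or quantile step. Window values were means of probes within 250 bp either side of each probe. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on window brightness), with a dye term coded so that the effect is the mean of both orientations with equal weight. A site was a run of at least 3 probes with a Benjamini-Hochberg adjusted p below 0.01, a positive effect, and an effect at least 3 robust SDs above the median of all windows. The threshold came to 0.56, from a robust SD of 0.19 taken below the median. Runs less than 500 bp apart were joined. Depleted regions used the same rule with the sign turned, with the robust SD taken above the median, so their threshold was not the 0.56 of the sites. Summits are maxima over many windows, so their effects are biased upward, and the values on arrays of the other orientation do not share this bias. Intervals of 95% are from limma's moderated standard errors. These draw on the variance of all windows, so at a site where the arrays differ widely the interval understates their spread.

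Named sites were, by a rule set before the data were examined, the 15 with the highest summit effect, the highest on each chromosome and the highest within 10 kb of chromosome ends, 18 in all. Other sites named in the text were chosen after their values were seen. Site shares at ends were tested with 10000 circular shifts within chromosomes, spacing with 10000 random placements (2000 for the alternatives), per-array means with the exact sign-flip test over 7 arrays (smallest possible two-sided p 0.0156), and counts per chromosome with the exact binomial test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

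The alternatives were normexp, loess, between-array scaling, the authors' score, no dye term, a slide term, each orientation alone, other windows, thresholds, p-values and run lengths, filters on dim and saturated probes, and each array left out. Normexp used the median spot and background signals with an offset of 50, since the files hold no mean spot signal, which the plan had named. Alternatives added after the data were seen were windows of at least 3 probes, leaving out or keeping only the 3 arrays with a ChIP channel brighter than 10000, sites held out by orientation, and further site sets for the spacing. The fit was tested on simulated data made from the real residuals. Seeded sites of 0.5 on the log2 scale lie below the threshold and were not called. The fit recovered 98.5% of sites of 1 and 100% of sites of 1.5 on the log2 scale. These were seeded on a flat background, and no size between 0.5 and 1 was seeded. So recovery at 0.84, the median summit value of the real sites, was not tested. It called 99 sites away from the seeded ones, on a background made of the real effects with the sign turned. These can be the real depleted regions, so they give no rate of false calls. Of dye effects of 0.4, 98.5% were recovered. The number of arrays limits the precision of all values.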

Results

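The origin recognition complex (ORC) is the protein complex that marks replication origins along eukaryotic chromosomes. Its binding profile was measured in the yeast Candida albicans by chromatin immunoprecipitation (ChIP) followed by hybridisation to a tiling array. Unsynchronised log-phase cultures, grown for 3 h at 30 °C in rich medium to an optical density of about 0.8 to 1, formed a single group of 7 replicates. On each 2-colour array, DNA precipitated with a polyclonal ORC antibody was set against genomic DNA from whole-cell extract, which is the control channel of every value below. The precipitated DNA carried Cy3 on arrays 1, 2, 5 and 6 and Cy5 on arrays 3, 4 and 7. Each array held 176619 probes on the 8 chromosomes, with a median spacing of 80 bp over 14.3 Mb. The median spot brightness of the ChIP channel ranged from 3385 on array 7 to 25843 on array 2, and was 45.7 to 198 times the local background. Positions are those in the probe names, and the genome build behind them is not given in the sources used here.

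The first comparison asked where ORC-precipitated DNA exceeded whole-cell extract. DNA precipitated with the ORC antibody was enriched at 349 sites, 24.5 per Mb, on all 8 chromosomes. None of the 7 arrays held a control precipitation, so enrichment by other means than ORC binding was not tested. The sites had a median span of 480 bp (quartiles 310 and 804 bp) and together covered 1.69% of the probed span. The median summit value was 0.84 on the log2 scale, a 1.79-fold enrichment, and 87 sites reached 1 or more. In 324 of the 349 sites all 7 arrays had a positive summit value, and in 345 at least 6 did. The sites were called on these same arrays, so such counts follow in part from the rule. By a threshold of each array's own, 3 robust SDs above its median, 26 sites passed on all 7 arrays. On at least 4 arrays 180 passed, and 10 passed on none. The same rule with the sign turned gave 118 depleted regions, so enriched sites were 2.96 times as many as depleted ones. The limits were not equal, as each side takes its robust SD from the other side of the median. The smallest summit value was 0.605 in size among depleted regions and 0.561 among enriched sites. At an equal limit, a fixed effect of 1, there were 59 enriched and 2 depleted regions. The sites came from limma's moderated test with Benjamini-Hochberg adjustment, and the largest adjusted p at a summit was 0.00952. An adjusted p below 0.01 was common, in 25714 windows with a positive and 27090 with a negative effect. Sites numbered 353 at an adjusted p below 0.05 and 343 below 0.001, so the effect limit did most of the selecting. The excess was absent with ChIP in Cy5 only, at 225 enriched against 251 depleted regions, and nearly so at 2 robust SDs, at 749 against 741. With normexp on the raw median spot signals, in place of the processed intensities, the rule gave 580 enriched and 25 depleted regions, and the enriched share of all calls rose by over 10 percentage points. That share was also higher at 4 robust SDs (183 against 12), with windows of 500 bp (336 against 42) and without the 3 brighter arrays (397 against 56). It was lower with windows of 100 bp (338 against 186).

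**Figure D1:**
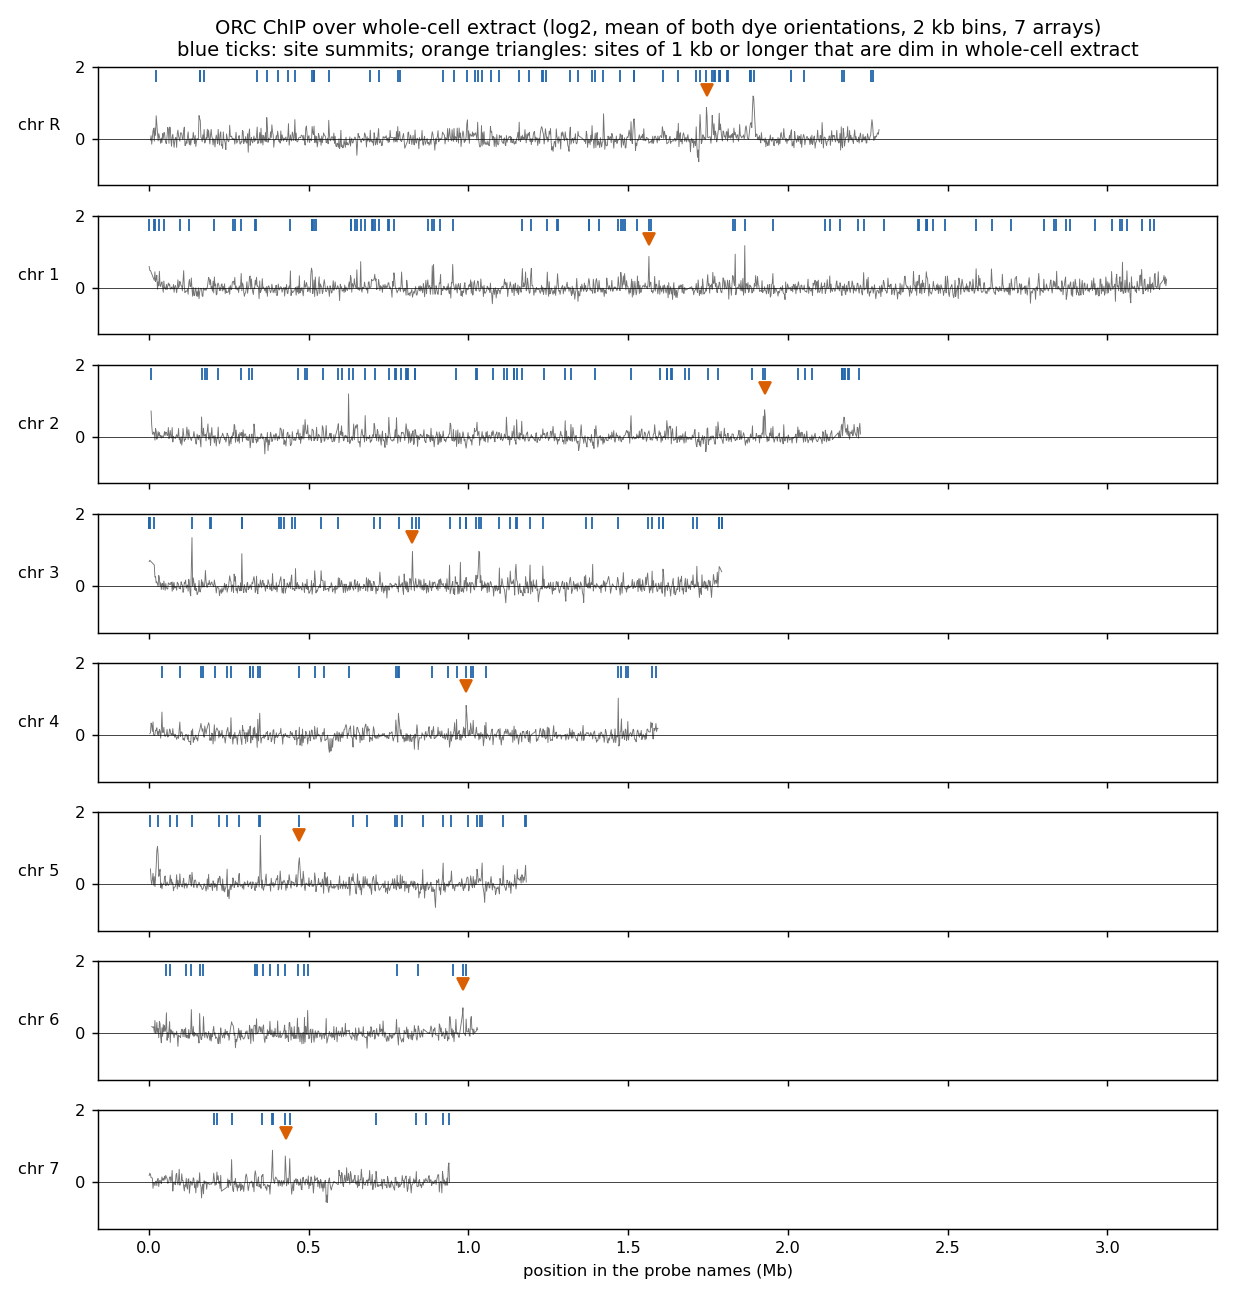
Mean log2 ratio of ORC ChIP over whole-cell extract (y axis) in 2 kb bins along the 8 chromosomes (x axis, Mb), as the mean of both dye orientations over 7 arrays. Blue ticks mark the summits of the 349 enriched sites, and orange triangles mark 8 sites of 1 kb or longer that were dim in whole-cell extract, 1 on each chromosome.

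The strongest site lay on chromosome 1 between 1864111 and 1865552, with a summit at 1864951. ORC enrichment there was 3.05-fold (95% interval 2.59 to 3.60, limma adjusted p = 9.3e-11), and the plain mean over the arrays was 1.55 ± 0.65 on the log2 scale (SD, n = 7). The site on chromosome 3 from 1574991 to 1575871 followed at 3.03-fold (95% interval 2.59 to 3.54). A 2960 bp site on the same chromosome, from 133111 to 136071, reached 2.85-fold (2.41 to 3.37). On chromosome 2 the site from 624071 to 626456 reached 2.77-fold (2.45 to 3.12), and that from 1922071 to 1923231 reached 2.70-fold (2.41 to 3.03). Chromosome 5 held 3 of the 15 strongest sites. Their summits were at 856890 (2.72-fold, 2.43 to 3.05), at 348591 (2.68-fold, 2.37 to 3.03) and at 1108551 (2.42-fold, 2.08 to 2.80). Chromosome R, which carries the ribosomal DNA repeats in this species, also held 3, with summits at 1763751 (2.56-fold, 2.26 to 2.90), 1158951 (2.51-fold, 2.26 to 2.79) and 1895071 (2.43-fold, 1.93 to 3.06). The other strong sites of chromosome 1 had summits at 1195751 (2.53-fold, 2.32 to 2.75), 1835110 (2.46-fold, 2.17 to 2.79) and 1168191 (2.44-fold, 2.21 to 2.70).

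The strongest site of chromosome 4, from 470871 to 471076, had 2.57-fold enrichment (95% interval 2.15 to 3.07). Its summit value was 0.25 on array 2 and between 1.01 and 2.14 on the other arrays, and the whole-cell extract of its summit window lay at −3.58 (log2 against the array median). The strongest site of chromosome 6 had its summit at 132550 (2.33-fold, 1.98 to 2.75), and that of chromosome 7 at 212351 (2.23-fold, 1.93 to 2.58). At the site of chromosome 1 with the summit at 1195751 the arrays lay closest together among the 18 named sites, with a mean of 1.32 ± 0.17 (SD, n = 7). At 17 of the 18 named sites all 7 arrays were positive, and the exception was chromosome R at 1895071, where array 2 had −0.04. Of the 18 named sites, 11 overlapped a called site in all 29 alternatives, 5 in 28, the site of chromosome 4 in 25 and chromosome R at 1895071 in 23. The last was not called with normexp, after loess, by the authors' score, without the dye term, with ChIP in Cy3 only or on the 3 arrays with the brighter ChIP channel. At the summit window itself, 2 sites had an adjusted p above 0.01 under some setting. Chromosome R at 1895071 had an adjusted p of 0.0152 without the dye term and 0.0130 on the 4 arrays with ChIP in Cy3, against 8.8e-07 with all arrays and the dye term (limma). On the 3 arrays with the brighter ChIP channel alone, its value was 0.52 (adjusted p = 0.0496), and that of chromosome 6 at 132550 was 0.41 (adjusted p = 0.0101). Over all alternatives their adjusted p ranged from 2.35e-09 to 0.0496 and from 1.81e-10 to 0.0101.

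**Figure D2:**
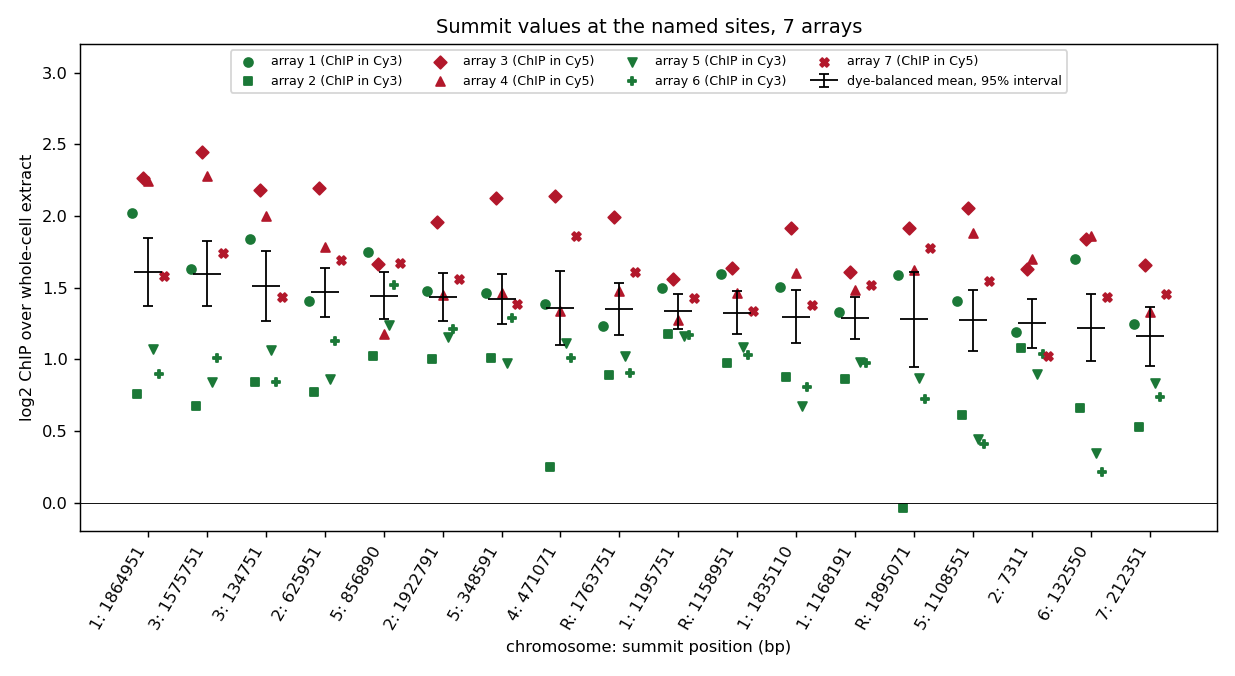
Summit value at the 18 named sites (x axis, chromosome and summit position) as log2 ChIP over whole-cell extract (y axis). Each symbol is 1 of 7 arrays, green for ChIP in Cy3 and red for ChIP in Cy5, and black bars are dye-balanced means with 95% intervals from limma, between 1.16 and 1.61.

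Most sites were short, and 17 of the 349 spanned 2 kb or more, a length chosen after the values were seen. These longer sites had a median summit value of 1.08, against 0.83 for the rest. The longest was on chromosome R, from 1888948 to 1896951, a span of 8003 bp. Over this span the whole-cell extract was brighter than the array median by 1.02 to 2.10 on the log2 scale (7 arrays), against means of 0.19 and 0.43 in 20 kb stretches to its left and right. The median ratio in it was 1.70 to 2.16 on the 3 arrays with ChIP in Cy5, 1.30 on array 1, and −0.83, 0.43 and −0.01 on arrays 2, 5 and 6. The next longest sites were on chromosome 5, from 23591 to 29445 (2.29-fold, 95% interval 2.01 to 2.61), and on chromosome 3, from 1031008 to 1035951 (2.08-fold, 1.85 to 2.34).

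Long sites that were dim in whole-cell extract were also counted by chromosome. Among the 63 sites of at least 1 kb, 8 had a summit window dimmer in whole-cell extract by more than 0.8 (log2) than the array median, and these 8 lay on 8 different chromosomes. Both limits were chosen after the values were seen, and the next longest site that was as dim spanned 924 bp. At 1 kb, a dimness limit of −0.5 gave 9 sites on 8 chromosomes and one of −1 gave 6 on 6, and at 2 kb the limit of −0.8 gave 7 on 7. With no length limit 56 sites were as dim. The 8 sites ran from 1744471 to 1747111 on chromosome R, 1563631 to 1566054 on chromosome 1, 1926671 to 1928951 on chromosome 2 and 823671 to 825911 on chromosome 3. On chromosomes 4, 5, 6 and 7 they ran from 992791 to 994736, 469151 to 471271, 981009 to 983311 and 426711 to 428711. ORC enrichment at their summits was alike, from 1.98-fold on chromosome 5 to 2.33-fold on chromosome 3, with a mean of 2.14-fold. Averaged over each whole site, the ratio was 0.92 ± 0.04 on the arrays with ChIP in Cy3 and 0.85 ± 0.07 on those with ChIP in Cy5 (SD over the 8 sites).

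**Figure D3:**
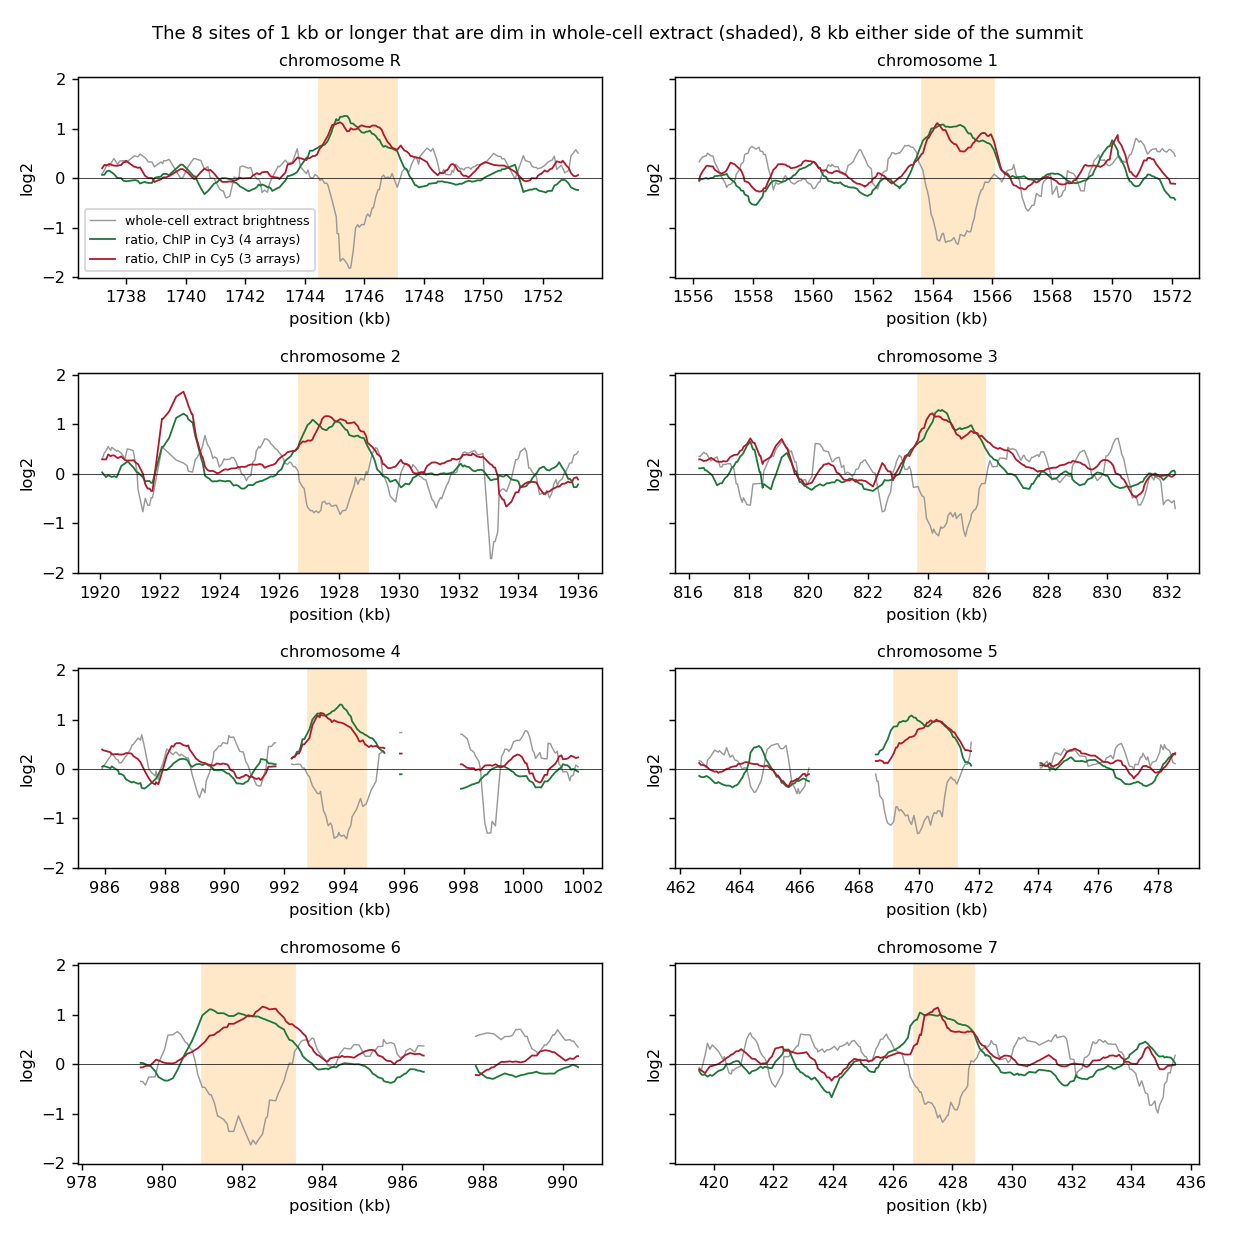
The 8 long sites dim in whole-cell extract (shaded) with 8 kb either side of each summit, by position in kb (x axis). Green and red lines are the mean log2 ratio on the 4 arrays with ChIP in Cy3 and the 3 with ChIP in Cy5, grey is whole-cell extract brightness against the array median (log2), and lines break where probes are over 500 bp apart. Over the shaded sites the mean ratio was 0.92 in Cy3 and 0.85 in Cy5.

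Sites called on one dye orientation were then measured on the cultures of the other. The 247 sites called on the 4 arrays with ChIP in Cy3 averaged 0.90 there and 0.80 on the 3 other arrays, and 229 of them were positive. The 225 sites called on the 3 arrays with ChIP in Cy5 averaged 1.15 there and 0.71 on the 4 other arrays, and 223 of them were positive. The 68 depleted regions called with ChIP in Cy3 averaged −0.85 there and −0.54 on the other arrays, and 65 of them were negative. The 251 called with ChIP in Cy5 averaged −0.96 there and −0.11 on the other arrays, and 166 were negative.

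**Figure D4:**
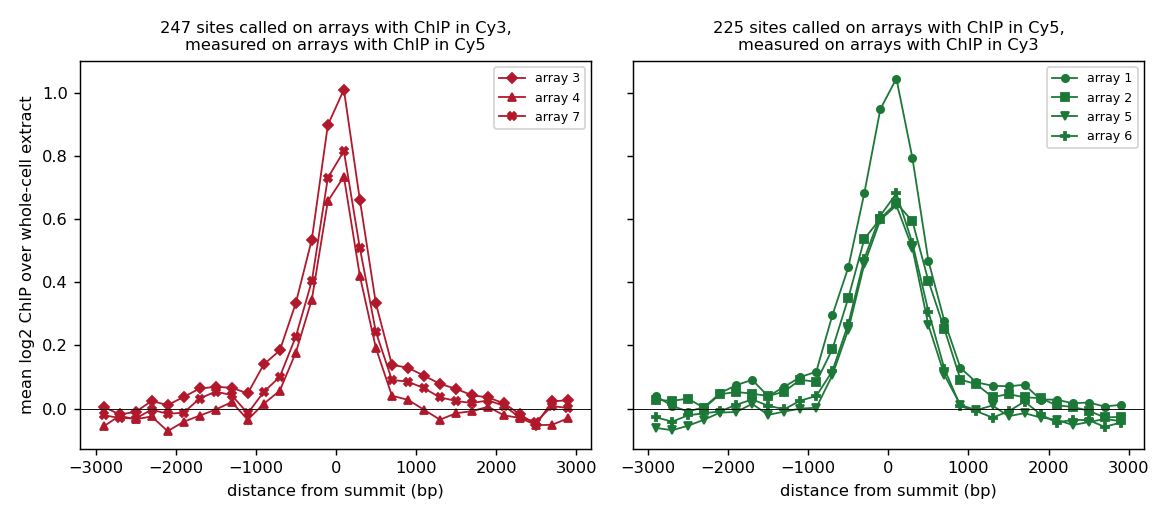
Mean log2 ratio (y axis) by distance from the summit (x axis, bp, 200 bp bins) for sites called on one dye orientation and measured on the arrays of the other, 1 line per array. Each line peaks within 200 bp of the summit, in both directions of the test.

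The deepest depleted regions were on chromosome 4 from 570831 to 571511 and on chromosome 6 from 271751 to 271877, where summit values were −1.38 and −1.28. The other depleted region below −1 was on chromosome 6 from 426071 to 426391, at −1.03. The longest, on chromosome R from 1719591 to 1722255, spanned 2664 bp with a value of −0.996. In 113 of the 118 depleted regions all 7 arrays were negative, on the same arrays that called them. The median span was 229.5 bp, against 480 bp for the enriched sites.

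The density of sites ran from 28.7 per Mb on chromosome 2 (64 sites) to 13.7 per Mb on chromosome 7 (13 sites). The count on chromosome 7 was below the 22.4 sites that its share of probes gives (exact binomial p = 0.0376), and the difference did not pass correction over the 8 chromosomes (Benjamini-Hochberg p = 0.301). The other 7 chromosomes had adjusted p-values of 0.558 or higher. The widest stretch without a site was 414 kb on chromosome 4, between the summits at 1054311 and 1468791. On chromosomes 6, 7 and 1 the widest stretches were 278, 270 and 258 kb.

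Neighbouring summits were a median of 24.2 kb apart (quartiles 9.48 and 53.7 kb), against 27.2 kb for sites placed at random probe positions. The coefficient of variation of the distances was 1.195, against 1.01 at random, so the spacing was less even than random placement (two-sided permutation test, p = 0.0014). Distances under 5 kb made up 14.96% of the 341, against 12.0% at random (one-sided permutation p = 0.0545). The difference in the coefficient did not pass with sites at 2 robust SDs (1.08, permutation p = 0.0550), after loess (1.102, p = 0.0800) or on the arrays with ChIP in Cy3 (1.00, p = 0.895).

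Chromosome ends were compared with the rest of each chromosome. Within 10 kb of the ends lay 11 of the 349 sites (3.15%), against 3.70 sites in random circular shifts (permutation test, p = 0.0054). The strongest was on chromosome 2 from 7311 to 7511, with 2.38-fold enrichment (95% interval 2.11 to 2.68), and its value was 0.90 to 1.70 on the 7 arrays. Of the 11, 5 were on chromosome 3, 3 at its left and 2 at its right end. All windows within 10 kb of an end averaged 0.18 ± 0.22 above the rest (SD, n = 7, exact sign-flip p = 0.125). The arrays differed widely, with 0.41, 0.43 and 0.33 on arrays 3, 4 and 7, 0.19 on array 1, and −0.02, −0.07 and −0.04 on arrays 2, 5 and 6. The mean of both orientations was above 0 at all 16 ends, from 0.001 at the left end of chromosome R to 0.68 at that of chromosome 3. At 4 ends all 7 arrays were positive (exact sign-flip p = 0.0156 each, the smallest that 7 arrays allow, 0.0625 after correction over the 16 ends). By the same permutation test the share after loess was 1.31% of sites, against 1.06% in random shifts (p = 0.806). At 4 robust SDs it was 2.73% (5 of 183 sites), 2.45 times the random share, without passing the test (permutation p = 0.124). The share passed at 2 robust SDs (2.67%, permutation p = 0.001), with normexp (3.10%, p = 0.0012) and with ChIP in Cy5 only (4%, p = 0.005). With ChIP in Cy3 only, 1 of 247 sites lay at an end (0.405%, against 1.11% in random shifts, permutation p = 0.469). The shifts place sites by position, whereas the ends were thinly probed, with 22 to 94 windows in each. So the random shares are too high for sites that need probes, and 1 site cannot show a share below random.

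**Figure D5:**
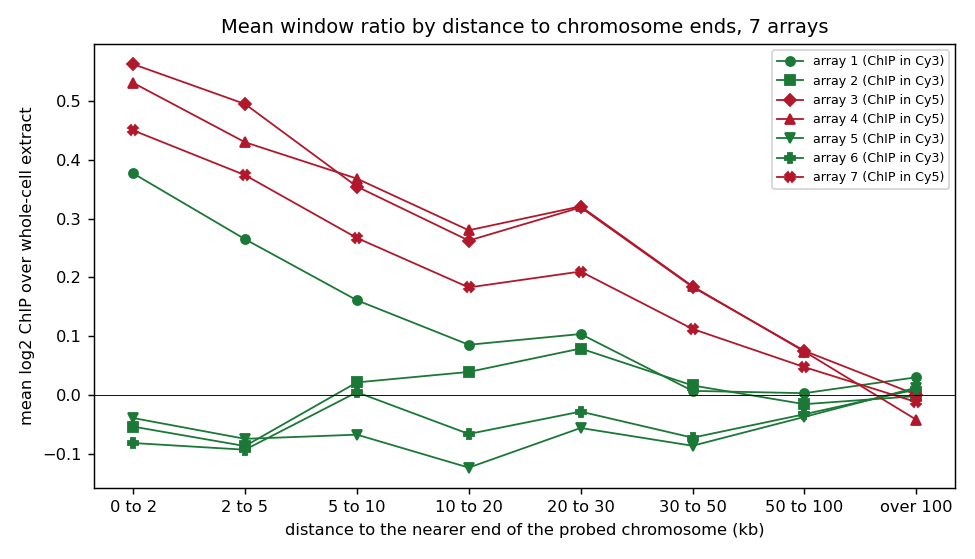
Mean log2 ratio (y axis) by distance to the nearer end of the probed chromosome (x axis, kb), 1 line per array, green for ChIP in Cy3 and red for ChIP in Cy5. Within 2 kb of the ends arrays 1, 3, 4 and 7 lie between 0.38 and 0.56, and arrays 2, 5 and 6 between −0.08 and −0.04.

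The site on chromosome 3 from 290322 to 291132 was called at 2.36-fold (95% interval 1.68 to 3.31), but its value differed between slides. It was 3.63, 2.64, 0.84 and 1.04 on arrays 1 to 4 (slide 1) and −0.03, 0.62 and 0.39 on arrays 5 to 7 (slide 2). Over 290221 to 291422 the whole-cell extract lay at −4.07 (log2 against the array median) on slide 1 and at −0.61 on slide 2. The site on chromosome 6 with its summit at 336928 (2.32-fold, 1.72 to 3.12) had −0.86 on array 2 and 0.53 to 2.38 on the others. Both were chosen after their values were seen. Their intervals are from limma's moderated standard errors, which draw on the variance of all windows. So they do not measure the spread of the 7 arrays at these 2 sites.

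Replicate arrays were compared over all windows. The Pearson correlation across windows, which are not independent replicates, was 0.65 in the median of 9 pairs of the same dye orientation and 0.29 in the median of 12 pairs of opposite orientation. Dye orientation changed 40984 of the 176619 windows (limma, adjusted p below 0.05). With dye in the fit, 25 windows differed between slides, all higher on slide 1, a count that other splits of the arrays reached too. Of the 25, 7 lay on chromosome 3 from 290551 to 290951, 10 on chromosome 5 from 1042711 to 1043471, 6 on chromosome R from 1517111 to 1517431 and 2 on chromosome 7. On each array, 28.9% to 84.8% of the 349 sites lay above the array's own threshold, with a mean of 51.3% ± 23.4 (SD, n = 7). The mean over all sites was 1.13, 0.98, 0.94 and 0.92 on arrays 3, 1, 4 and 7, and 0.63, 0.65 and 0.69 on arrays 2, 5 and 6.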

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

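All tests in this part were chosen after the result was seen, except those of the spots next to the chromosome 3 probes and of the ends after loess. The results that stood out were a sample far from the others and a signal in the control channel. At chromosome 5, summit 348591, array 3 had 2.12, while the next highest array had 1.47 and the lowest 0.97. Chance gives such a gap in about 1 of 20 groups, and 1 of 38 tested groups had it. No explanation was tested for it.

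In whole-cell extract, which the comparisons use only as the divisor, the 18 probes of chromosome 3 from 290221 to 291422 had a mean of −4.069 on slide 1 and −0.61 on slide 2 (log2 against the array median). Set against 5 kb on both sides, the whole-cell extract of slide 1 was lower by a mean of −3.283, with −4.95, −4.10, −0.83 and −3.25 on arrays 1 to 4, while slide 2 was at 0.19 ± 0.05 (SD, n = 3). ORC binding alone would leave the whole-cell extract of the slides alike, and slide 1 was lower than slide 2 by −3.469 (SE 0.89), in probes chosen for that difference. Whether ORC was bound besides cannot be told apart by the ChIP channel, which on slide 1 was also lower than its flanks, by −1.254 ± 1.06 (SD, n = 4), with 0.20 on array 3. On arrays 1, 2 and 4 the whole-cell extract was so low that binding as strong as at the strongest site (1.61 on the log2 scale) would not have lifted it above them, and array 3 is a single array. A fault of the slide at these spots is argued against by the 249 spots next to them, which differed between slides by −0.01669. What stays open, besides such binding, is a low copy of the sequence in the cultures of arrays 1, 2 and 4. It is a candidate explanation that the slide 1 mean of −3.283 goes with and that was found from these data. Array 3, also on slide 1, had only −0.83, so the loss did not follow the slide as a whole. A low copy alone would lower both channels of a culture alike and leave the ratio unchanged. The median ratio of the region was 3.31, 2.21 and 1.60 (log2) on arrays 1, 2 and 4. So a low copy alone leaves the raised ratio unexplained. To the right of the region, the 10 probes from 291586 to 292271 were near local background in whole-cell extract on all 7 arrays (median spot 0.53 to 1.59 times background), so their log2 values are floor values, and no explanation was tested for this stretch. In the region itself the median spot was 2.61, 3.72, 55.7 and 8.41 times background on arrays 1 to 4, so the size of the loss is uncertain on arrays 1, 2 and 4. Part of it lay within the right flank, whose median on slide 1 was −0.43 with it and −0.26 without it. The design names no difference between the cultures, so no biological group was tested.

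Ratios at chromosome ends differed between arrays, from −0.07 on array 5 to 0.43 on array 4. A dye bias of equal size in both orientations would cancel, and the mean of both was 0.2034 with an SE of 0.03. Ratios compressed evenly on arrays 2, 5 and 6, whose ChIP channel was brighter, would leave the end value divided by the site value alike, and it was lower on them by −0.4099, at −0.07 ± 0.04 (SD, n = 3) against 0.34 ± 0.11 (SD, n = 4). A bias that follows spot brightness stays open, since loess left 35.94% of the end value. It could account for part of the pattern, and no biological explanation was tested.

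Other splits of the arrays were counted. Of the 35 splits into 4 and 3 arrays, 1 had as many windows as the split by dye orientation, the dye split itself with 40984. The highest other, arrays 1, 5 and 6 (all with ChIP in Cy3) against the rest, had 9010. The dye split ranked first, but 35 splits allow no share below 1 of 35, so the count alone cannot exclude chance. For slide, 3 of 34 splits, with dye in the fit, had as many as the 25 windows of the real one, and the highest other had 93, so chance is not excluded. With the signs of arrays turned in 64 patterns, 2 had as many sites as the real one with 349. The other was the pattern that follows dye orientation, with 589, a structure of the arrays that the dye term takes out of the real fit, and none of the other 62 had more than 1. Turning some signs sets signal shared by the arrays against itself, so low counts could hardly have failed to come out. They give no rate of false calls, and they cannot separate binding from a bias shared by all arrays.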

How the results depend on the processing

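Alternatives with the 3 brighter arrays, windows of at least 3 probes, the array correlation and the per-array share, and site sets for the spacing other than 2 and 4 robust SDs, were chosen after seeing the data. The cause of each change was not tested, except that thresholds, run lengths and subsets of arrays change counts by their construction. The 349 enriched sites became 580 with normexp, 749 at 2 and 183 at 4 robust SDs, 59 with a fixed effect of 1, 225 with ChIP in Cy5 only, and 194 on the 3 arrays with the brighter ChIP channel. Leaving out 1 array gave 295 to 393, and the remaining settings lay within 1.5 times the count. The authors' score called 289, and 278 of the 349 overlapped one of them. The 118 depleted regions became 25 with normexp, 68 with ChIP in Cy3 only, 251 with ChIP in Cy5 only, 186 and 42 with windows of 100 and 500 bp, 741 at 2 and 12 at 4 robust SDs, 2 with a fixed effect of 1, 50 with runs of 5, and 56 without and 77 with only the brighter arrays. Leaving out 1 array gave 80 to 159. The median correlation between arrays was 0.41, and 0.77 with ChIP in Cy5 only. A mean of 51.3% of sites passed an array's own threshold, against 27.9% of the normexp sites, 28.3% of those at 2 and 67.2% of those at 4 robust SDs. Dye orientation changed 21179 windows after loess and 63641 with normexp, and 0 windows differed between slides with normexp (limma, 6266 at an unadjusted p below 0.05) against 25 (10441). The share of sites at ends, 3.15%, was 1.31% after loess, and 2.73% at 4 robust SDs, where 183 sites were tested (permutation p = 0.124). With ChIP in Cy3 only it was 0.405%, which is 1 of 247 sites. It was 2.67% at 2 robust SDs, 3.10% with normexp and 4% with ChIP in Cy5 only (permutation p = 0.001, 0.0012 and 0.005). The coefficient of variation of spacing was 1.08 at 2 robust SDs, 1.102 after loess and 1.00 with ChIP in Cy3 only. For the 18 named sites, 507 of 511 values under alternatives kept their direction and an adjusted p below 0.01, and 4 kept only the direction. Settings that changed only thresholds, p-values or run lengths reused the main fit, so their part of the 511 could not change. Tests at tRNA genes, centromeres, intergenic regions, base composition, motifs and gene lists were not run, for want of an annotation in the array's build. Each ratio pairs ChIP with whole-cell extract of the same culture, and with 1 group no pairing between groups was possible. ChIP spots were at least 45.7 times background in the median, and binding weaker than the 0.56 (log2) that a site needs is not covered.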

Other observations

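All tests in this part were chosen after the result was seen. The 8 long sites that were dim in whole-cell extract, 1 per chromosome, invite a hypothesis, since each chromosome of this yeast has 1 centromere. Whether they fall on different chromosomes more often than chance was not settled, since the limits of length and dimness were picked on the same data. Over the 9 limits tried, the exact probability that sites placed at random by probe number fall on as many chromosomes ran from 0.00123 to 0.1609. Dim hybridisation alone would raise other dim stretches as well, but of 883 bins of 2 kb as dim as the sites, 0.1133% lay above the threshold, and their mean ratio was −0.02 ± 0.13 (SD over bins). A dye bias would change sign with orientation, and the sites averaged 0.9179 with ChIP in Cy3 and 0.85 with ChIP in Cy5. But the sites were called on the mean of both orientations, from which a bias of equal size cancels. Opposite signs could hardly have come out, so these values are no separate test of dye bias. A candidate explanation is that these are the centromeres. It was not tested, as no centromere annotation was used here.

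Among the probes outside the chromosomes, 3 sequences, numbered 21, 22 and 23 in the probe names, were brighter than the array median in whole-cell extract on every array, by 1.05 to 2.12 on the log2 scale. Their mean ratios were 0.52, 0.77 and 0.62 on the arrays with ChIP in Cy5 and −0.31, −0.43 and −0.30 on those with ChIP in Cy3. The negative means came from arrays 2, 5 and 6, the arrays with the brighter ChIP channel, while array 1, also with ChIP in Cy3, was near 0, at 0.02, −0.004 and 0.07. Sequence 65 was dimmer, and its ratio was 0.08 ± 0.06 (SD, n = 7, exact sign-flip p = 0.0156, the smallest that 7 arrays allow), positive on 7 of 7 arrays. The exact sign-flip test gave p = 0.797, 0.75 and 0.594 for sequences 21, 22 and 23, and these p-values were not corrected over the 4 sequences.

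Whole-cell extract of 1 array or more departed from the median of the 7 arrays by over 1 (log2) in 4 of 6953 bins of 2 kb. One was the chromosome 3 region above, and the other 3 were neighbours on chromosome R from 1884000, where array 2 was higher by 1.08 to 1.19.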
